A study of Mus musculus with 2 samples.

How the data were processed

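DNase-seq was performed by the study on liver of adult C57BL/6J mice in constant darkness, with a protocol that isolates nuclei from crosslinked tissue per the labels. The 2 libraries were technical replicates 1 and 3 of 1 biological sample, and the sex of the animals is given as not collected. The deposited files belong to the series as a whole, and their descriptions list both libraries' data under each, so no value could be tied to a library. They were made from 2 alignments to mm10. The aligner, the peak, hotspot and footprint callers and their versions and settings are not given in the sources used here.

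The values were used as deposited. Each of the 3 deposited peak tables gives a signal per peak, its height in the authors' value: whole numbers for the first alignment, and for the second alignment whole multiples of 0.00618, a scaling that the authors do not describe. The deposited hotspot table gives the −log10 of a false discovery rate, a q-value, per hotspot, limited at 100. The deposited footprint table gives the same p-value, a false discovery rate of 0.01, for every footprint, and no score for any of them. The 2 deposited per-base tables give a false discovery rate, a p-value of the corrected kind, for each run of bases and list only those below 0.05. They hold no cleavage counts, so the agreement between them was measured on the mean −log10 false discovery rate per bin of 1 kb, limited at 100 and with 0 for bases not listed. No read counts were held, the depth of the libraries is unknown, and no interval or limit that needs it is given. The 3 peak tables and the other tables lay inside the chromosome lengths of GRCm38, the reference used, on all chromosomes.

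Consensus peaks were the peaks of the deposited set with the most peaks, that of the first alignment, of which at least 50% lay in a peak of each of the other sets. Genes and starts were taken from GENCODE mouse release 21, protein-coding genes only (21938). A promoter peak was a consensus peak that touched the 500 bp on either side of any annotated start of the gene, and the tallest such peak gave the gene's height. That start can lie far inside the gene, so the height need not be that of the outermost start. Distal peaks lay more than 500 bp from any start, in the gene and 10 kb on each side. Location was given by the centre of the peak in the order promoter, exon, intron and intergenic, over the share of placed bases.

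The 17 gene lists were the core clock and clock output, hepatocyte identity and plasma proteins, bile acid and cholesterol metabolism, glucose and glycogen metabolism, fatty acid synthesis and oxidation, xenobiotic metabolism, Kupffer cell and macrophage markers, liver endothelial markers, stellate cell and fibroblast markers, bile duct epithelial markers, lymphocyte markers, red cell lineage markers, neuronal and glial genes, muscle genes, housekeeping genes, immediate early and stress genes, and the HoxA cluster. Ahsp, of the red cell list, was not in the annotation under that symbol. Tfrc was in 2 lists. The lists, the 30 recognition words, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named all clock genes, the 3 genes of every other list with the tallest promoter peak, up to 2 genes without a promoter peak, the 10 genes with the most distal peaks per length among spans of at least 30 kb, and the 5 longest hotspots. The values of some genes that the rule names are not reported here.

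Promoter counts of each list were compared with all other protein-coding genes by a two-sided Fisher's exact test, and shares have exact Clopper-Pearson 95% intervals. The median number of distal peaks of each list was set among 10000 random lists of the same size, drawn from genes of the same decile of span length, with a two-sided p whose smallest value is 0.0002. Words were searched on either strand in footprints with 5 bp on each side. The 243682 footprints inside consensus peaks of the full 150 bp (65.7% of all) were compared with 100 random placements of intervals of the same length in the same peaks, two-sided by distance from their mean, with a smallest permutation p of 0.0099. The clock genes with an E box, D box or ROR element in any deposited footprint of their span, with its flank, were counted against 10000 random lists matched on the number of peaks. Benjamini-Hochberg adjustment ran over the 17 lists, the 30 words or the 3 elements, at a threshold of 0.05. Random placement keeps the composition of the peak but does not model the sequence preference of DNase I.

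The alternatives set beforehand were other promoter windows and flanks, the upper 50% of peaks by height, each deposited peak set alone, a background matched on promoter CpG, other overlap rules, footprints without flank or distal only, other bins and scales, and clock lists matched on the number of footprints. Alternatives chosen after seeing the data were promoter footprints only, words with the same letters in another order (up to 10 per word, those found at least 20 times in 10 placements on average), listed bases per bin, clock lists matched on the number of peaks and promoter CpG together, and clock words wholly inside a footprint. The methods were tested on simulated data. The promoter test called 4.50% of lists with no change and 98% of lists with a planted change, the distal test 2% and 86%, and the clock element test 0% and 56%. The motif search found 1006 footprints with a word written into 1000, at a ratio of 5.09, and a control word was at 0.979. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1. Alignments and coverage signal were not used here.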

Results

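Chromatin accessibility was measured by DNase-seq in the liver of adult C57BL/6J mice, 8 to 10 weeks old, kept in constant darkness for 50 h and sampled at circadian time 38. DNase-seq maps the DNA that the nuclease DNase I can reach in nuclei, and inside such DNA it leaves footprints, short stretches protected from cleavage, where proteins are bound. The libraries numbered 2 and were technical replicates 1 and 3 of 1 biological sample, so the data held 1 group with no contrast between conditions and no replicate error. The deposited tables could not be tied to single libraries and gave no read counts, so the depth of each library is unknown. They held 208664 peaks and 176184 hotspots from a first alignment, and a wider set of 199667 peaks, a narrower set of 146756 peaks and 370733 footprints from a second alignment. The wider and the narrower set both had a median peak length of 200 bp and differed in stringency. Every peak of the narrower set held a base at a false discovery rate under 0.001. In the wider set 74.6% of peaks did so, and in the first alignment's set 74.1%. Accessible DNA shared by all 3 peak sets came to 138247 consensus peaks covering 20.7 Mb, with a median length of 150 bp and a median height of 191 in the authors' value. With a single circadian time, no rhythm could be tested, and genes were compared with other genes inside the same tissue. Genes are not independent replicates, and the intervals given for shares of genes cover counting error only.

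The core clock stood open in this liver. Of 22 core clock and clock output genes, 21 had a consensus peak within 500 bp of an annotated start (95.5%, exact 95% interval 77.2 to 99.9), against 60.5% of all other protein-coding genes. The tallest promoter peaks of the list were at Nr1d2, which encodes the repressor REV-ERBβ (height 1831, rank 137 of all consensus peaks, chromosome 14, 18239136 to 18239285 in mm10), and at its relative Nr1d1 (1563). The genes of the negative limb were at 1512 for Per1, 1418 for Cry2, 1295 for Per2, 910 for Per3 and 762 for Cry1. Arntl, which encodes the activator BMAL1, reached 1497 and its partner Clock 483. Among the output genes that encode PAR bZIP factors and their competitor, Tef reached 1445, Dbp 1371, Nfil3 637 and Hlf 600, while Ciart reached 1283, Bhlhe40 819, Bhlhe41 442 and Rora 508. The casein kinase genes were at 904 for Csnk1d and 268 for Csnk1e, the lowest of the list. Some of these heights belong to internal starts. The Rora peak began at 69289716 on chromosome 9, in a gene that starts at 68653786. That of Csnk1e began at 79425536 on chromosome 15, in a gene read leftward from 79455566. Heights in the other lists can be internal in the same way. For scale, the tallest promoter peak of an autosomal gene had a median height of 674. Npas2, the paralogue of Clock, was the exception. Its nearest consensus peak at the main start lay 920 bp away (height 699). A peak at 262 bp, of height 51 in the first alignment's set, did not meet the 50% overlap rule of the consensus, and in each of the 3 deposited sets alone, or with a window of 1000 bp, all 22 clock genes (100%) had a promoter peak, so this exception depended on the rule and the window. The excess of open clock promoters passed the two-sided Fisher's exact test (adjusted exact p = 0.000581 over 17 lists). Clock promoters were rich in CpG, with a median observed over expected ratio of 0.618, and 79.1% of genes drawn from the same CpG quartiles had a promoter peak, against which the excess was no longer past the threshold (adjusted permutation p = 0.0800, with adjusted p from 4.5e-05 to 0.0800 over all alternatives).

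Every gene in the 5 lists of hepatocyte identity and metabolism had a promoter peak. All 28 genes of hepatocyte identity and plasma proteins had a promoter peak (adjusted exact p = 2.4e-05), among them Ahsg, which encodes the plasma protein fetuin-A (height 1256), Cebpa (1185) and Tdo2, a tryptophan-degrading enzyme (1145). The 21 genes of bile acid and cholesterol metabolism were all open (adjusted exact p = 0.000186), the tallest at Srebf2, the regulator of cholesterol synthesis (1522), Hmgcs1 (1405) and Nr0b2, which encodes the repressor SHP (1286). The same held for the 17 genes of glucose and glycogen metabolism (adjusted exact p = 0.000581), with Gys2, the liver glycogen synthase, at 1529, Mlxipl at 1348 and Slc37a4 at 1339. All 22 genes of fatty acid synthesis and oxidation had a peak (adjusted exact p = 0.000186), led by Angptl4 (2114, rank 42), Acly (1469) and Cpt1a (1453). All 21 genes of xenobiotic metabolism did so too (adjusted exact p = 0.000186), with Por, the electron donor of the cytochromes P450, at 1712 and Gstm1 at 1423. Ugt1a1, the enzyme that conjugates bilirubin, had the tallest peak of that list (3088, rank 18), inside a stretch of chromosome 1 with 29 consensus peaks whose median height was 920. In each of these 5 lists the exact 95% interval began at 80.5% or higher. Against genes of the same promoter CpG content, of which 38.4 to 67.8% were open, all 5 excesses passed at a permutation p of 0.0002, the smallest that 10000 random lists can give (adjusted permutation p = 0.000567). With a window of 200 bp the share was 96.4% for hepatocyte identity and 94.1% for glucose metabolism, and in the upper 50% of peaks by height it was 90.9% for fatty acid metabolism, with the calls kept.

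The lists of genes used in nearly every cell and of the immediate early and stress response were also fully open. All 20 housekeeping genes (adjusted exact p = 0.000278) and all 18 immediate early and stress genes (adjusted exact p = 0.000399) had a promoter peak. The tallest were Rplp0 (1397), Ywhaz (1350) and Rpl13a (1317) in the former list, and Jun (1845), Hsph1 (1594) and Atf3 (1467) in the latter. Immediate early promoters had a median CpG ratio of 0.738, and against genes of equal CpG content, 86.2% of them open, their excess did not pass (adjusted permutation p = 0.167, from 0.000323 to 0.167 over all alternatives).

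Genes of other lineages were less often open. Among lymphocyte markers, 3 of 15 had a promoter peak (20%, adjusted exact p = 0.00373), namely the T cell kinase gene Lck (496), Pax5 (320) and Ptprc (64), whereas Cd3e and Cd8a had none. Among skeletal and heart muscle genes, 3 of 18 did so (16.7%, adjusted exact p = 0.000581), namely Mylpf (1030), Myh4 (458) and Tnni2 (47), and the myogenic factors Myf5 and Myf6 had none. Of the red cell genes, 2 of 10 were open (20%, adjusted exact p = 0.0274), Tfrc (1207), which is also in the housekeeping list, and Alas2 (125), on the X chromosome, and the globin genes Hba-a1 and Hba-a2 had no peak. In the HoxA cluster, 3 of 11 genes had a low promoter peak (27.3%, adjusted exact p = 0.0434), at Hoxa7 (241), Hoxa10 (104) and Hoxa5 (90), and Hoxa11 and Hoxa13 had none. The Lck and Pax5 peaks lay at internal starts on chromosome 4. They began at 129556556 and 44645316, in genes read leftward from 129573641 and 44710487. Against genes of equal CpG content the lymphocyte and red cell calls were lost (adjusted permutation p = 0.167 and 0.471, ranges over all alternatives 0.000926 to 0.167 and 0.00976 to 0.471). The red cell share was 30% with a window of 1000 bp, or in the first or the wider peak set alone, and was then not past the threshold (adjusted exact p = 0.0637, 0.0600 and 0.0612). The HoxA share depended on the peak set, with 72.7% of the genes open in the wider set of the second alignment alone and 63.6% in the first alignment's set alone, and with a window of 200 bp its call was lost (adjusted exact p = 0.0760).

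Markers of the other cells that liver tissue holds were open in part, and none of their lists passed the test, with shares that depended on the peak set. Kupffer cell and macrophage markers were open at 8 of 15 genes (53.3%, adjusted exact p = 0.641), the tallest being Cd68 (179), C1qb (115) and C1qa (86), while Tyrobp and the X-linked Vsig4 had no peak. Liver endothelial markers were open at 9 of 15 (60%, adjusted exact p = 1), including Stab2, a scavenger receptor of sinusoidal cells (686), Fcgr2b (335) and Egfl7 (188), but not Sox18 and Stab1. The Stab2 and Egfl7 peaks lay at internal starts. That of Stab2 began at 86878836 on chromosome 10, in a gene read leftward from 87008025. That of Egfl7 began at 26591116 on chromosome 2, in a gene read rightward from 26580014. For stellate cells and fibroblasts the count was 5 of 14 (35.7%, adjusted exact p = 0.117), at Col1a1 (445), Lrat, which stores vitamin A (113), Reln (71), Dcn (57) and Rgs5 (40), with Hand2 and Lum lacking a peak. Bile duct epithelial markers were open at 5 of 12 (41.7%, adjusted exact p = 0.270), among them Sox9 (881), Onecut1 (810), Spp1 (294) and Epcam (35), and Cftr and Cldn7 had none. Dcn, Rgs5, Spp1 and Epcam fell outside the rule for named genes and were named after their values were seen. The neuronal and glial comparison list had 7 of 18 open genes (38.9%, adjusted exact p = 0.115), with Olig1 (559), Dlx1 (442) and Gfap (343) tallest and Neurod1 and Neurod6 without a peak. The background mattered here: against genes of equal CpG content, of which 24.1% were open, the Kupffer markers were above (adjusted permutation p = 0.0329), and the neuronal list, against 78.2%, was below (adjusted permutation p = 0.000567), with ranges over all alternatives of 4.5e-05 to 1 and 0.000567 to 0.665. Peak height mattered too, since in the upper 50% of consensus peaks by height the open share fell to 0% for Kupffer, 13.3% for endothelial, 7.14% for stellate and 16.7% for neuronal genes, all below the other genes. In the first or the wider peak set alone, the Kupffer share was 86.7% (adjusted exact p = 0.148 and 0.147) and the endothelial share 80% (adjusted exact p = 0.325 and 0.303), higher than the other genes without passing the threshold, and the stellate share was 64.3% and 50% (adjusted exact p = 1 and 0.303). The stellate share was below with a window of 200 bp (28.6%, adjusted exact p = 0.0445, from 0.00103 to 1 over all alternatives).

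**Figure D1:**
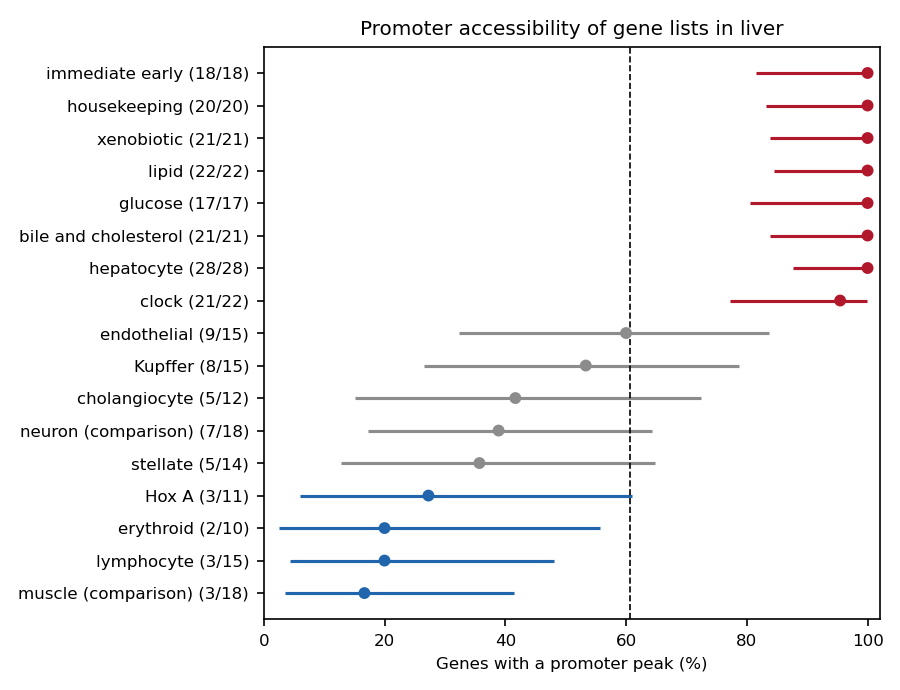
Share of each gene list with a consensus peak within 500 bp of an annotated start, in percent, with exact 95% intervals as lines and counts of genes in brackets; the dashed line is the share of all protein-coding genes, 60.6%. Red lists were above and blue lists below the other genes at an adjusted p under 0.05, grey lists were not past it. The clock, hepatocyte and metabolic lists lie at 95.5% or more, and the muscle, lymphocyte, red cell and HoxA lists at 27.3% or less.

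The liver lists also stood out away from promoters. Genes of hepatocyte identity had a median of 18 distal peaks in the gene and 10 kb on each side, against 2 in random lists of genes of the same span length (95% range 1 to 3). Medians were 11 for fatty acid metabolism against 3, 10 for glucose metabolism against 3, 8 for bile acid and cholesterol metabolism against 3 and 8 for xenobiotic metabolism against 2. Clock genes had a median of 9.5 against 3 (1.5 to 5), from 3 at Per3 to 21 at Per2 and Hlf and 92 at Rora, whose span is 754.5 kb long. For these 6 lists no random list was as extreme (permutation p = 0.0002, the smallest that 10000 lists can give, adjusted permutation p = 0.000567). Neighbouring genes of a list, such as Fga, Fgb and Fgg or Abcg5 and Abcg8, can count the same distal peaks. Random lists matched on span length alone do not allow for this, so the p values of such lists may be too small. The immediate early list had 4.5 against 1 (adjusted permutation p = 0.000971) and the housekeeping list 4 against 2 (adjusted permutation p = 0.0259). Counting inside the gene alone, both had a median of 1 and were not past the threshold (adjusted permutation p = 0.0830 and 0.592, ranges 0.000567 to 0.0830 and 0.00425 to 0.592), and the housekeeping list was not past it either in the upper 50% of peaks by height (2, adjusted permutation p = 0.119). The other 9 lists were not past the threshold: medians were 6 for endothelial, 2 for stellate, cholangiocyte, lymphocyte and neuronal, 1.5 for red cell and 1 for Kupffer, muscle and HoxA genes. The medians themselves moved with the flank and the peak set, for hepatocyte genes from 8.5 inside the gene alone to 36 with 50 kb of flank and for clock genes from 4.5 to 17.5, with both lists above random lists throughout.

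Catalase, bile acid uptake and apolipoprotein B genes were among those with the densest distal accessibility. Among the 14164 genes with a span of at least 30 kb, the median was 5.84 distal peaks per 100 kb and the 99th percentile 35.4. The 10 densest genes were Errfi1 (109 per 100 kb), an inhibitor of EGF receptor signalling, Cat (101.3), which encodes catalase, Ahcy (96.6), Sdc4 (95.9), Sc5d (91.8), an enzyme of cholesterol synthesis, Mgst1 (90.6), Mat1a (86.3), the S-adenosylmethionine synthetase of adult liver, Usf2 (82.4), Slc10a1 (81.6), the bile acid uptake transporter, and Apob (81.1). Cat held 52 distal peaks in 51.3 kb and Apob 48 in 59.2 kb. The longest hotspot ran for 26.1 kb on chromosome 19 (5825874 to 5851995) and overlapped the lincRNA gene Neat1, the antisense gene Frmd8os and Frmd8, and it held 39 consensus peaks. The next 4 lay at Sdc4 (14.9 kb), Errfi1 (12.4 kb), Tat, which encodes tyrosine aminotransferase (11.8 kb), and Tnrc18 (11.7 kb).

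**Figure D2:**
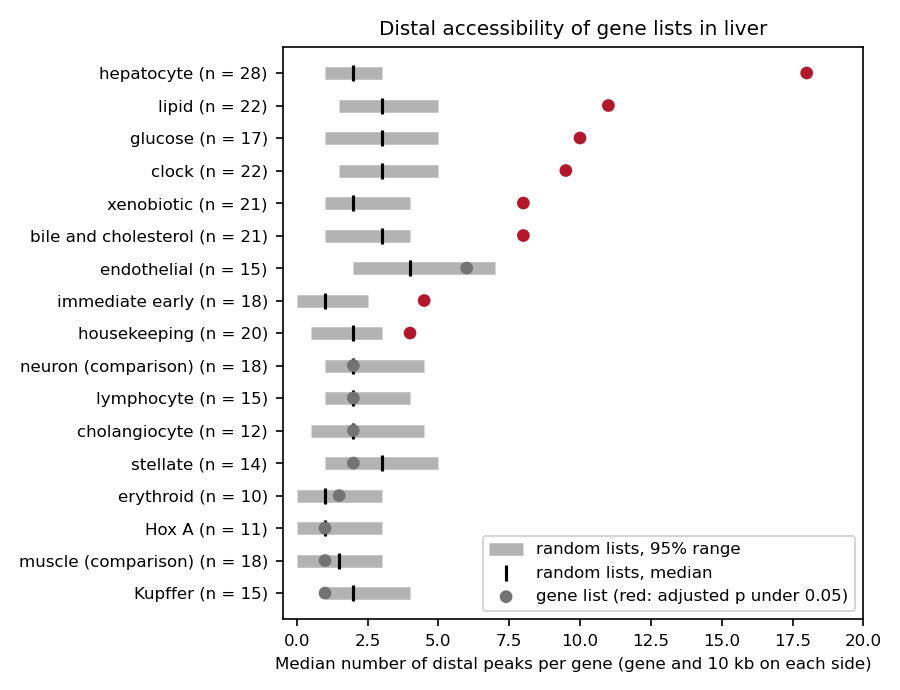
Median number of distal consensus peaks per gene in each list (points, in the gene and 10 kb on each side, more than 500 bp from any start), with the 95% range of 10000 random lists matched on span length as grey bars and their median as a tick. Red points passed an adjusted p of 0.05. Hepatocyte genes lie at 18 against a random median of 2, and the clock list at 9.5 against 3.

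Promoters held 17.6% of consensus peaks, 5.42 times their share of the genome, and their peaks were tall, with a median height of 373. Introns held 44.9% (1.12 times, median height 174), intergenic sequence 31.9% (0.5999 times, 163) and exons outside promoters 5.58% (1.52 times, 183). No test was run on these shares. The promoter share was 24.5% among the upper 50% of peaks by height and 24.3% with a window of 1000 bp. Promoter peaks also differed between chromosomes. On the X chromosome the 380 open genes had a median promoter height of 357.5, against 674 on the autosomes, whose medians ran from 630 on chromosome 13 to 742 on chromosome 17. Density was 20.6 peaks per Mb on X and 44.0 to 80.7 on the autosomes, and the Y chromosome held 45 consensus peaks.

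**Figure D3:**
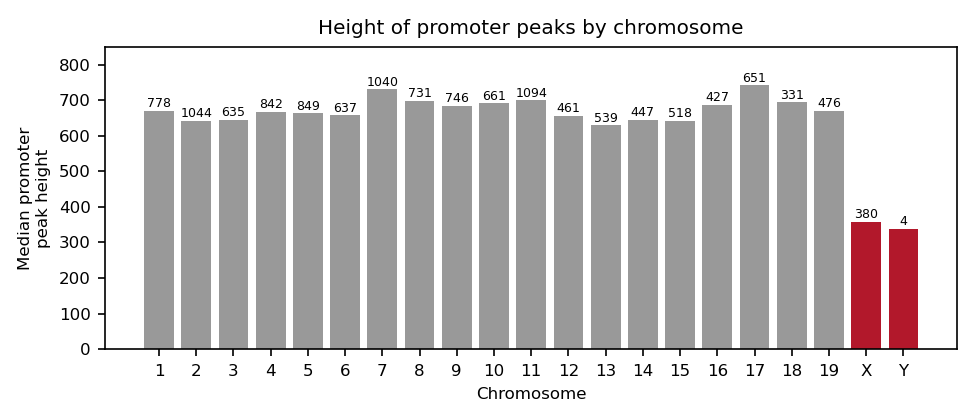
Median height of the tallest promoter peak per gene, in the authors' value, for each chromosome; the number above each bar is the number of genes with a promoter peak. The 19 autosomes lie between 630 and 742, X at 357.5 and Y, with 4 genes, at 338.

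DNA words that clock factors read lay in or beside footprints around clock genes, counted in footprints with 5 bp on each side. An E box (CACGTG), the element bound by CLOCK and BMAL1 and by other bHLH factors such as USF, lay in a footprint or its flank at 15 of 22 clock genes, against a median of 5 (95% range 1 to 9) in random lists matched on the number of peaks. A ROR element (AWNTRGGTCA, where W is A or T, R is A or G and N any base), read by ROR and REV-ERB receptors, did so at 6 clock genes against 1 (0 to 3). Both passed at a permutation p of 0.0002, the smallest that 10000 lists can give, and at an adjusted p of 0.000300 over 3 elements. A D box (TTAYRTAA, where Y is C or T), the word of DBP, TEF, HLF and NFIL3, was found at 6 genes against 3 (0 to 6), which did not pass (adjusted permutation p = 0.0748), while the number of D box footprints did, with 10 against 3 (0 to 8, adjusted permutation p = 0.00820). Counting only words wholly inside a footprint, a test chosen after these results had been seen, the E box was at 8 genes against 2 (0 to 5, adjusted permutation p = 0.00480), the D box passed with 5 against 1 (0 to 4, adjusted permutation p = 0.0174), and the ROR element call was lost, with 1 against 0 (0 to 1, adjusted permutation p = 0.271). Clock, Csnk1d and Csnk1e were among the genes with none of the 3. The random lists were not matched on how often a word occurs in the DNA. The counts therefore do not show that the words were protected more than the DNA around them.

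Footprints with an E box in them or their flank numbered 38, of which 10 held it whole, at 8 genes, and 18 lay in promoters, 12 in introns, 4 in exons and 4 in intergenic sequence. Footprints on either side of an E box can share it through their flanks, and the 38 held 33 distinct E boxes. Nr1d1 had 5 distinct E boxes, the most of the list, with 4 at Per1 and 3 each at Dbp, Ciart, Tef and Hlf. At Per1 the footprint at 69094871 to 69094885 on chromosome 11, read with 5 bp on each side, was CCGCGTGAGCCAGCCTGCACGTGTT, 339 bp from the start, with 3 of the 6 bases of the E box in the flank, and the footprint overlapped the peak of height 1512. At Dbp the footprint at 45707703 to 45707724 on chromosome 7, 175 bp from a start in a peak of height 1009, held the whole E box and read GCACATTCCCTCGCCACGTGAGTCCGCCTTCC. At Cry1 it lay 50 bp from the start, at 85185108 to 85185120 on chromosome 10 in the peak of height 762, again with the whole E box, and read GCACCCCACGTGACCACCGGCAC. Nr1d1 had E box footprints in introns 1175 to 2298 bp from the start, and in a peak of height 889 upstream of the gene a single E box lay between 2 footprints, from 98783537 and 98783546, with 3 and 2 of its 6 bases inside them. The 7 ROR footprints were all intronic, and only that in Rora held the whole element. A pair of them lay in an intron of Cry1, from 85161915 and from 85161958, in a single peak of height 643, and the others were in Arntl, Cry2, Npas2, Nfil3 and Rora. Whole D boxes lay in promoter footprints of Per3 and Nr1d2 and in introns of Nr1d1, Nfil3 and Rora, while 4 of the 8 bases of the D box at the Per2 promoter (footprint 91459435 to 91459445 on chromosome 1, CCGTCGCTCTCTTTACATAAG with the flanks, peak height 1295) lay outside the footprint. The Nr1d1 D box lay in the tallest peak of the gene's span (1778, rank 181).

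The E box is a palindrome with CG at its centre, and other such words were counted in the same way, with the flank. Of the 15 other palindromes of 6 bases with CG at the centre, 3 were above the range of random lists, CGCGCG at 11 genes against 4 (1 to 8), GCCGGC at 10 against 4 (1 to 8) and AGCGCT at 7 against 3 (0 to 6), and only the first passed the threshold (adjusted permutation p = 0.0192, 0.0832 and 0.181 over 16 words, against 0.00320 for the E box).

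**Figure D4:**
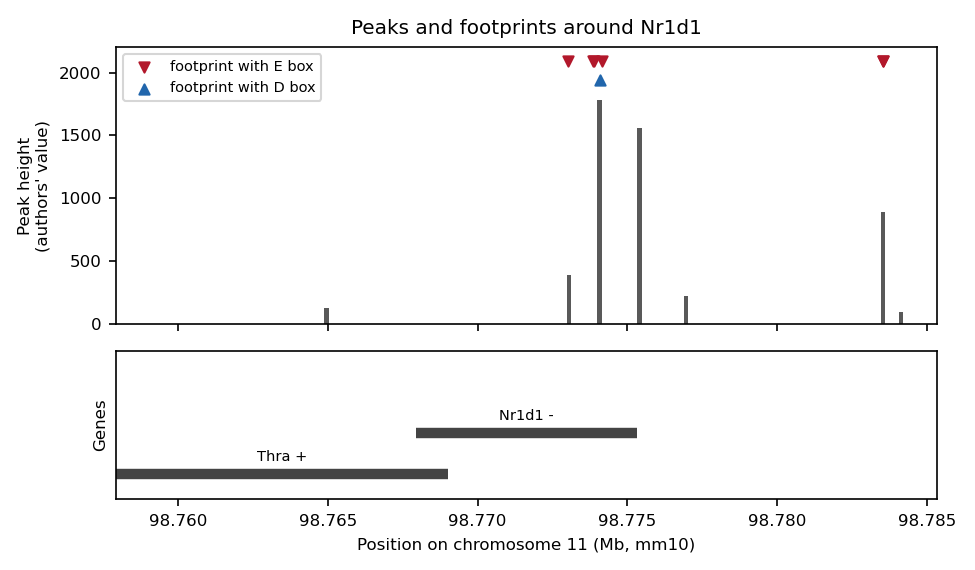
Consensus peaks (grey bars, height in the authors' value, drawn at their width) in Nr1d1 and 10 kb on each side, chromosome 11, position in Mb of mm10, with footprints that have an E box (red) or a D box (blue) in them or within 5 bp as markers and genes with their strand below. The D box lies in the tallest peak, of height 1778, and the 2 red markers in the upstream peak of height 889 share 1 E box.

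Across the genome, footprints with 5 bp on each side held the words of nuclear factor I, CTCF, C/EBP and HNF4A at more than 2 times the rate of random placement. The nuclear factor I word had the highest ratio to random placement inside the same peaks, 4.81 (83 footprints). CTCF, which organises chromatin loops, followed among common words with 3.58 (4835 footprints). The hepatocyte factors HNF4A and HNF1 were at 2.62 (1134 footprints) and 2.29 (104), C/EBP at 2.84 (220) and the DR1 element of PPAR and HNF4A at 2.84 (112). The D box reached 1.93 (981), the CREB word 2.38 (592), NRF1 2.43, SP and KLF 2.28 (2432), RFX 4.47 (13), YY1 1.92 (43), ETS 1.51 (126), STAT 1.32 (1203) and NF-Y 1.20 (3349). The E box was at 1.39 (1700 footprints against a mean of 1225) and the ROR element at 1.21 (278 against 229.8). Of 30 words, 21 were above random placement, 7 below and 2 not past the threshold, DR4 (2.19, 8 footprints, adjusted permutation p = 0.0717) and AP-1 (0.976, adjusted permutation p = 0.376). Below were GATA (0.407), MEF2 (0.465), FOXA (0.476), the glucocorticoid receptor word (0.573), POU (0.647), the E box relative CATGTG (0.8004) and PU.1 (0.840). Of the 4 words included for comparison, REST (1.73) and MYOD (1.16) were among the 21 above and MEF2 and POU among the 7 below. Whether factors that read the REST and MYOD words were bound here was not tested, so these words do not measure false calls. Passing this test does not by itself show that a liver factor was bound. Nor does a ratio below 1 show that a factor was absent, since the sequence preference of DNase I was not modelled. Two-sided permutation p was 0.0099, the smallest that 100 placements can give, for all words above or below but PU.1 (0.0198) and, above, the IR1 element of FXR (2.52, 8 footprints, p = 0.0297).

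Letter composition set a limit on these ratios. Words made of the same letters in another order were run for 22 of the 30 words, and nuclear factor I, RFX, DR1, DR4, IR1, HNF1, NRF1 and YY1 had none, so that their ratios lack this control. The D box lay above all of its 10 shuffled words (highest 1.15), as did the CREB word (10 words, highest 1.55) and STAT (10 words, 1.31). Fewer words could be used for HNF4A (4 words, highest 0.952), C/EBP (7 words, 2.35), ETS (4 words, 1.15) and REST (2 words, 1.73 against 1.72). These also lay above all of theirs, as did CTCF against a single shuffled word (1.498). The E box lay inside its range of 0.872 to 1.51, the ROR element inside 0.424 to 1.28, SP and KLF inside 1.95 to 2.38, MYOD (1.16) inside 0.793 to 1.55, and FOXA inside 0.425 to 1.07. Only GATA and the glucocorticoid receptor word lay below all of theirs (lowest 0.418 and 0.684). The flank mattered for many words. Without its 5 bp the ratio was 7.11 for CTCF, 12.3 for nuclear factor I, 8.43 for DR1, 8.33 for RFX, 5.77 for C/EBP, 5.61 for NRF1, 4.82 for HNF1, 4.36 for HNF4A, 4.17 for SP and KLF and 3.89 for the CREB word. It was 0.151 for FOXA, 0.0719 for GATA, 0.267 for POU, 0.307 for the glucocorticoid receptor word and 0.404 for PU.1. The ROR element was then at 0.886 and IR1 at 3.51, neither past the threshold, while DR4 (5.33) was above and AP-1 (0.869) below. Among promoter footprints alone, the ROR element (0.894), IR1 (0), MYOD (1.00), MEF2 (0.696) and glucocorticoid receptor (0.437) words were not past it and AP-1 was below (0.752), and among distal footprints alone DR4 was above (2.25) and AP-1 was at 1.01, not past the threshold.

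**Figure D5:**
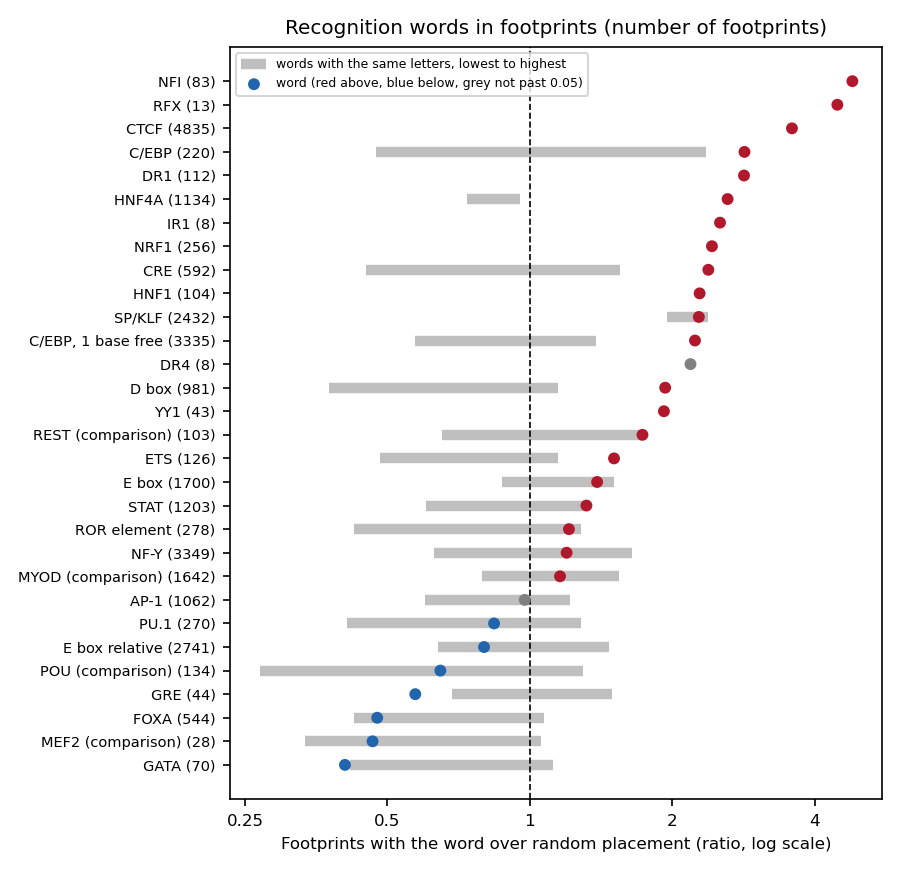
Ratio of footprints that hold each word to the mean of 100 random placements inside the same peaks, log axis, number of footprints in brackets; red points were above and blue points below random placement, grey points not past an adjusted p of 0.05. Grey bars run from the lowest to the highest ratio of words with the same letters, where more than 1 could be run. HNF4A at 2.62 lies above its bar, which rests on 4 words, and the E box at 1.39 inside its own, which rests on 10.

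The deposited peak sets overlapped in most of their peaks. Of the first alignment's peaks, 86.9% had at least 50% of their length in the wider set of the second alignment (Wilson 95% interval 86.8 to 87.0), and 83.6% of the wider set's peaks lay in the first (83.4 to 83.7). The Jaccard index of covered bases was 0.572. Of the narrower set, 98.3% lay in the wider. The share of the wider set in the first depended on the rule, with 94.6% at an overlap of 1 bp and 20.4% at 90% of the peak, since the wider set's peaks are longer. Over 157645 peaks matched within 25 bp, heights correlated across loci with Pearson r = 0.995 and Spearman rho = 0.999. The per-base tables listed 79.7 and 76.7 Mb with a Jaccard index of 0.887, and over 1 kb bins their mean −log10 false discovery rate correlated with r = 0.938 and rho = 0.952. Loci are not independent replicates, and no p is given. The descriptions list both alignments under both libraries, so whether this is agreement between libraries or between processings of the same reads is not known.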

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

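Footprints outside all 3 deposited peak sets numbered 19748. They are given here only because the comparison of recognition words did not use them, a choice made after the number was seen, and no test was run on them. Of these, 19380 lay inside a deposited hotspot. No explanation for them was tested.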

How the results depend on the processing

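The alternatives that used promoter footprints only, shuffled words, listed bases per bin, clock lists matched on both peaks and CpG, or clock words wholly inside a footprint were chosen after seeing the data, and the others were planned. No paired analysis was possible because the files hold 1 biological sample. Leaving out a replicate could not be run because no table could be tied to a library. A stricter footprint score was not run because the table holds no score per footprint, and DR4 had no value among promoter footprints, where none was placed. What depth limits could not be stated, since no counts were held. Of 133 alternative values for promoter lists, 108 were classed as unchanged, as were 91 of 114 for distal lists, 83 of 95 for words and 10 of 12 for clock elements. For a single list, word or element, unchanged means the same direction and side of the threshold. The totals for lists and words also hold counts of lists or words called. For such counts a modest change in number was classed as unchanged. All changes follow, and except where the overlap rule, window or number of peaks fixes them, the cause was not tested.

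Against genes of equal promoter CpG the clock (95.5%), immediate early (100%), lymphocyte (20%) and red cell (20%) calls were lost, the neuronal list was below (38.9%), and the Kupffer list, lower than the other genes without passing the threshold, turned to above (53.3%) and the endothelial list (60%) to higher without passing. In the upper 50% of peaks by height, the lists below were 8 instead of 4, with endothelial (13.3%), Kupffer (0%), neuronal (16.7%) and stellate (7.14%) added, and the housekeeping distal median of 2 was not past the threshold. In the first set alone 2 lists were below, with red cell (30%) and HoxA (63.6%) lost, and Kupffer (86.7%) and endothelial (80%) turned to higher than the other genes without passing. In the wider set alone 2 were below, with red cell at 30% lost, and HoxA (72.7%), Kupffer (86.7%) and endothelial (80%) turned to higher without passing. With a window of 1000 bp the red cell call was lost (30%), and with 200 bp the HoxA call was lost (27.3%) and the stellate list was below (28.6%). With no flank around genes the housekeeping and immediate early distal medians of 1 and 1 were not past the threshold. Distal lists that were never past it changed their side of the middle of the random lists: cholangiocyte (2.5), lymphocyte (4), red cell (1.5) and HoxA (1) in the first set alone, with the same 2.5, 4, 1.5 and 1 in the wider set alone, cholangiocyte (2) and HoxA (1) in the narrower, cholangiocyte (0.5), lymphocyte (1), neuronal (1) and HoxA (0) in the upper 50% by height, cholangiocyte (0), red cell (0), neuronal (1) and HoxA (0) with no flank, and lymphocyte (10) and HoxA (3) with 50 kb.

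Without flank around footprints, AP-1 (0.869) and DR4 (5.33) passed the threshold, IR1 (3.51) did not, and the ROR element turned below 1 without passing (0.886). Among distal footprints DR4 passed too (2.25), and AP-1 turned above 1 without passing (1.01). Among promoter footprints AP-1 passed (0.752), the glucocorticoid receptor (0.437), MEF2 (0.696) and MYOD (1.00) words did not, and IR1 (0) and the ROR element (0.894) turned below 1 without passing. Counting clock genes with the word wholly inside a footprint, the D box passed (5) and the ROR element did not (1), while the E box, at 8, did.

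Location shares, for promoter, exon, intron and intergenic in turn, were 14.8, 5.76, 46.3 and 33.1% in the first set alone, 15.02, 5.71, 46.4 and 32.9% in the wider set alone, 24.5, 5.38, 41.7 and 28.4% in the upper 50% by height, and 24.3, 4.43, 40.8 and 30.5% with a window of 1000 bp. The share of the first set in the wider, and of the wider in the first, was 91.3 and 94.6% at 1 bp, 74.0 and 20.4% at 90% of the peak, and 94.9 and 86.5% in the upper 50% of each set, with a Jaccard index of 0.605. All 12 values for the narrower set moved too: the first and the wider set in it, at 66.3 and 67.2%, ranged from 57.2 to 70.0% and from 55.7 to 73.1%, and its share in the first, at 87.3%, ranged from 20.5 to 97.2% and in the wider from 98.27 to 99.96%. Pearson r and Spearman rho between the per-base tables were 0.938 and 0.978 in 10 kb bins, 0.937 and 0.967 in bins with a value in both, and 0.956 and 0.936 for listed bases, and r was 0.967 on the log2 scale.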

Other observations

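The gene families described next and all tests in this part were chosen after the patterns they concern had been seen. Only for the tests of repeats and of the 90th percentile on X, of shared reads on chromosome 1, of CpG content at clock genes and of the other palindromes' count was the prediction written before the value of the test was known. The promoters of each family were set against all other genes, of which 60.4 to 63.8% were open. No background matched on promoter CpG was run for the families, although open shares ran from 15.3 to 86.1% over quartiles of promoter CpG. The sensory receptor genes of the nose had few open promoters. Of 1135 olfactory receptor genes, 25 had a promoter peak (2.20%, exact 95% interval 1.43 to 3.23), the tallest at Olfr56 (480), and of 331 vomeronasal receptor genes, 5 did so (1.51%, 0.492 to 3.49, adjusted p = 5.0e-124 by Fisher's exact test). Those 5 included Vmn1r4 with a height of 942, above the autosomal median. Keratin genes were open at 6 of 53 (11.3%, adjusted exact p = 2.9e-13), with the tallest peaks at Krt8 (604), Krt4 (469) and Krt18 (427), and Krt8 and Krt18 are the keratin pair of hepatocytes. At the other end, all 78 mitochondrial ribosomal protein genes (adjusted exact p = 4.1e-17) and all 28 RNA polymerase subunit genes (adjusted exact p = 2.8e-06) had a promoter peak, with Mrps14 at 1786 and Polr3gl at 1208, while neither family was past the threshold against random lists for distal peaks (adjusted permutation p = 1 for each).

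The antitrypsin-related serpins and the enzymes of glucuronidation had an excess of distal peaks, and their promoters were not past the threshold. Clade A serpins, which include the antitrypsin genes, had a median of 7 distal peaks against 1.5 in random lists (adjusted permutation p = 0.000667), with 23 at Serpina1c and Serpina3m, whereas 15 of 24 had a promoter peak (62.5%, adjusted exact p = 1). UDP glucuronosyltransferases had 7 against 4 (adjusted permutation p = 0.0490), with 16 of 21 promoters open (adjusted exact p = 0.259), and the spans of the Ugt1a genes overlap. In any family, the serpins included, neighbouring genes can count the same distal peaks. Random lists matched on span length alone do not allow for this, so these p values may be too small. The Cyp2c and Cyp3a enzymes (3 against 3.5, adjusted permutation p = 1), KLF factors (5 against 2, adjusted permutation p = 0.0656) and nuclear receptors (5 against 3, adjusted permutation p = 0.0707) did not pass, and for promoters these 3 families were at an adjusted exact p of 0.449, 0.275 and 0.0719. On the Y chromosome, Uty (613), Eif2s3y (347), Ddx3y (329) and Kdm5d (310) had promoter peaks, and their X-linked relatives Kdm6a (791), Eif2s3x (368), Ddx3x (471) and Kdm5c (931) were taller, while Usp9y and Zfy1 had none.

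Promoter peaks on the X chromosome were lower than on the autosomes, with a median of 357.5 against 674. Repeats marked by soft masking were argued against. Among peaks with no soft-masked base the ratio of X to autosomes, averaged over CpG quartiles, was 0.536 (bootstrap 95% interval 0.437 to 0.637). CpG makeup was argued against too, with a ratio of 0.515 (0.434 to 0.6005) over all promoter peaks. Near-identical copies that are not soft-masked were not tested for X promoters. A candidate explanation is 1 accessible X per cell against 2 copies of each autosome, as in males, which would scale all promoters alike, and the 90th percentile of heights was 697 on X against 1281, a ratio of 0.544 (bootstrap 95% interval 0.509 to 0.581), inside bounds of 0.4 to 0.7 that were set after the medians but before this ratio had been seen. The medians were known when the bounds were set, and the 90th percentile came from the same promoters, so a ratio inside them was likely beforehand. The ratio therefore does not favour 1 accessible X over any other cause that lowers X promoters alike. Genes on X were also less often open (40.1%, against 49.6 to 71.7% on the autosomes), which was not examined further. The ratio also cannot separate a male X from the inactivation of an X in females. Whether reads at the Y peaks came from homologues elsewhere was not tested, and the sex of the animals was not collected. The hypothesis of 1 accessible X predicts that X and Y promoters of homologous genes in a library of known males show the same ratio. A library of known females would show whether reads from elsewhere reach the Y peaks, but their absence there would not test this hypothesis.

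A stretch of 76.6 kb on chromosome 1 (88211816 to 88288365), over the 3′ part of the Ugt1a cluster, Mroh2a, Hjurp and Trpm8, held 14 of its 29 consensus peaks at or above the genome's 99th percentile of height (1365) and 7 of the 20 tallest peaks of the genome, with 9735 the highest; its edges were drawn after the peaks had been seen. Reads shared with copies elsewhere in the reference were argued against, with 1.29% of the 36-base words of these peaks found again. Processing by a single alignment was argued against too. The median ratio of second to first heights was 0.935, between the 5th and 95th percentiles of all matched peaks (0.895 and 1.04). Extra copies of the stretch in these animals could not be excluded. The 10th percentile of its heights was 95.4, above the median of 35.2 for runs of as many peaks and above 99.3% of them, but under the highest run (149). Extra copies predict a raised level between the peaks too, which read depth in DNA of the same animals would test, and no biological explanation was tested.

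E boxes lay in footprints or their 5 bp flanks at 15 of 22 clock genes against 5 in random lists, and wholly inside a footprint at 8 against 2, and the explanations were tested on the former count only. The lists were not matched on the number of E boxes in the DNA of the peaks. No random placement was run for the clock genes alone. More E boxes in the sequence therefore cannot be told apart from preferred protection of them. Promoter CpG was argued against as the cause, since with lists matched on both peaks and CpG the count of 15 stayed above the range of 1 to 9. A general excess of palindromes with CG at the centre could not be told apart from it: 0 of the 15 others had a ratio as large as the E box, which had been set beforehand as counting against this explanation, but CGCGCG, the only one of the 15 past the threshold (adjusted permutation p = 0.0192, with 0.00320 for the E box), came close, at 2.75 against 3. The difference between these ratios, compared only after the count of 0 had been seen, was 0.25 with a bootstrap interval of −1.25 to 1.6, which leaves it open. The hypothesis that CLOCK and BMAL1 may occupy E boxes at these genes predicts E box footprints that differ between circadian times. It also predicts that E box footprints weaken in liver without BMAL1, while CGCGCG footprints stay in both cases. The present data hold 1 time only.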
